A study of Homo sapiens with 4 samples.

How the data were processed

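The series is a ChIP-seq study of MCF-7 breast cancer cells with an antibody against PKC-theta, with total input chromatin as the control. The labels give 4 samples, 1 in each of 4 groups (PKC-theta ChIP and total input, each untreated or treated with 0.65 ng/ml PMA for 60 h), and the series' design text gives 2 technical lanes per library. Processed files were used for 1 sample, the PMA-treated PKC-theta ChIP, as 2 region lists without header lines. Lists of the untreated ChIP and signal of the inputs were not analysed here, so no comparison between groups was made.

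Human genome build hg19 and the tools cutadapt, Bowtie2, Picard, HTSeq and MACS2 are named, without versions, roles or order, in the submitters' processing notes. The name of the longer list names ZINBA, a peak caller that models windows of read counts with mixture regression, and the name of the shorter list says that all peak callers entered it. Which callers these were, their thresholds, whether inputs were subtracted and whether the lanes were pooled before calling are not given in the sources used here. Each deposited line holds a chromosome, a start, an end, a peak number and a whole number in the fifth column. In the fifth column the authors deposited a score from 0 to 9 whose meaning no header or label gives, with 81.4% of ZINBA regions and 52.1% of the shorter list at 0. All region borders fell on a grid of 125 bp, with starts 1 above a multiple and ends on a multiple, so positions were read as counted from 1. Apart from the fifth column, whose meaning is open, the lists carry no read counts, heights or p-values. The read depth is therefore unknown, and no value has an error from sequencing depth.

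The gene table supplied for this work is on another build (GRCh38.p14) than the lists (hg19), and no genome sequence was used. Results planned before the data were examined that need genes or sequence were for this reason not run. They are the share of regions at promoters, the share in exons, introns and intergenic sequence, the fixed gene lists (mesenchymal, epithelial, stem cell, immediate early, NF-kB, protein kinase C, luminal, T cell, housekeeping and olfactory receptor genes), the motif search, and GC and repeat content. Positions were described instead by chromosome, arm and cytogenetic band of hg19. The bands were taken from the band table of the R package circlize 0.4.16 under R 4.3.3. Shares of chromosomes and arms had been planned. Bands had been planned, for lists without an annotation of their build, only to name regions and windows. Tests of band shares, pale bands, neighbours and chromosome segments were not part of that plan. All 24 chromosome lengths of that table equalled the hg19 lengths of GenomeInfoDb 1.38.1. Bands of 3 classes (centromere, variable heterochromatin and acrocentric stalk) were left out of the counted sequence, as the nearest available stand-in for assembly gaps, which removed 35 ZINBA regions and 10 regions of the shorter list. A region belonged to the band that holds its centre.

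For each chromosome, arm and band the share of regions was compared with the share of counted sequence by an exact two-sided binomial test with Benjamini-Hochberg adjustment over all units of that kind and a threshold of 0.05, and folds carry Clopper-Pearson 95% intervals. Shares sum to the whole, so a lower share is relative. Centres of regions were placed at random 1000 times on their own chromosome, in the counted sequence, to test pale bands and neighbours within 10 kb (two-sided). Widths did not enter, because both measures use the centre alone. P-values of this placement test are labelled permutation p below, although positions were drawn evenly rather than permuted. The same test had been planned for the overlap of the lists, but its outcome was fixed because the shorter list is a subset of the ZINBA list, so it is not reported. Overlap meant at least 1 bp (bedtools 2.31.1). Shorter-list and ZINBA-only regions were compared by Fisher's exact test, adjusted over the 8 measures compared, and their widths by a permutation test with 100000 resamples. The width difference under other settings was tested with fewer resamples. Neighbouring regions are not independent, and some are overlapping pieces (2410 ZINBA regions remained after merging within 1 kb, and 96 shared their exact position with another number). The p-values are therefore smaller, and the intervals narrower, than independent sites would give. The tests say nothing about the treatment, since the unit is the region and there is 1 sample.

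Named regions follow a rule fixed before the data were examined for the case without an annotation of the lists' build, namely the 10 top regions by score or width and the 5 windows of 1 Mb with the most regions in each list. The rule put the score first and width where a list has none. Width was used in departure from it, because the meaning of the score is not given and most scores are tied at 0, and equal widths were ordered by position. The setting that keeps the upper part of a list departed from the plan in the same way. Bands and chromosomes were named in the text by their counts after the values were seen, as were the 4 segments known to be amplified in MCF-7 cells. Gene names given with a band are background knowledge of what the band holds. Other settings fixed before the data were examined were merging within 1 kb, keeping regions at or above the median width, leaving out chromosome Y, and overlap of 50% of the region or reciprocally. Settings chosen after seeing the data left out the 4 segments or chromosome 20, kept regions with a value above 0 in the fifth column, compared within chromosomes, placed regions over the whole genome, or used neighbours within 100 kb.

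Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9. The tests were tried on 200 simulated lists of 2945 regions placed independently and evenly over the counted sequence. Such lists lack the clustering of the real ones, so they do not give the rate of false calls for these data. With no effect a mean of 0.06 of 24 chromosomes was called. Chromosome 20 at 3 times its density, reached by adding regions, was called in 100% of simulations. Its mean recovered density was 2.97 times that of the other chromosomes. A simulated odds ratio of 2 for pale bands was recovered as 2.02.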

Results

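Chromatin bound by protein kinase C theta (PKC-theta) was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in MCF-7 cells, an established oestrogen receptor-positive human breast cancer line of luminal, epithelial type. PKC-theta is a signalling kinase best known from T cell activation, where it acts downstream of the T cell receptor. Phorbol 12-myristate 13-acetate (PMA) activates protein kinase C enzymes by standing in for diacylglycerol, and the series asks how PKC-theta on chromatin relates to genes that are switched on as breast cancer cells turn mesenchymal and take on stem cell traits. The series holds 4 samples with 1 per group, namely a PKC-theta ChIP and a total input from untreated cells and the same pair from cells given 0.65 ng/ml PMA for 60 h. Region lists were used from the PMA-treated ChIP sample alone, so the comparison of PMA-treated with untreated cells was not analysed here. There were no replicates, the read depth was unknown, and every test below describes where regions of this sample lie rather than an effect of PMA. Intervals are exact binomial 95% intervals and cover counting error alone, with regions taken as independent, which they are not.

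The PMA-treated sample had a longer list of 2945 regions, named after the peak caller ZINBA, and a shorter list of 795 regions, named as the product of all peak callers. All 795 regions of the shorter list had the same number, chromosome, start and end as a region of the ZINBA list, so the shorter list held 27.0% of the ZINBA list. The remaining 2150 regions are called ZINBA-only here. Peak numbers of the ZINBA list run to 9175, and 6230 of them have no listed region. All shares below therefore describe the list as given. The ZINBA regions covered 3.72 Mb, those in counted bands covered 0.130% of the counted sequence, and the shorter list covered 1.11 Mb.

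Regions of the shorter list were wider than ZINBA-only regions. Their mean width was 1440 ± 237 bp (SD over 795 regions) against 1333 ± 137 bp (SD over 2150 regions), a difference of 107 bp (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). In the shorter list 77.6% of regions were wider than the narrowest width class of 1250 bp, against 40.6% of ZINBA-only regions, an odds ratio of 5.07 (95% interval 4.19 to 6.15, Fisher's exact test, adjusted p = 8.13e-74). Merging regions that lay within 1 kb of each other turned the mean difference to -21.8 bp (permutation test, p = 0.547), and the difference was 39.4 bp among regions at or above the median width and 36.0 bp (permutation test, p = 0.0142) among those with a value above 0 in the fifth column of the list.

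ZINBA regions lay densely on chromosomes 20, 19, 3, 17, 1 and 16. Chromosome 20 alone held 586 of the 2910 counted regions, 9.65 times its share of the sequence (95% interval 8.96 to 10.4). After merging within 1 kb its fold was 7.83, below that interval, which takes regions as independent. The fold was 6.10 without 4 chromosome segments described in later paragraphs. It was 3.84 among regions with a value above 0 in the fifth column of the list, where chromosome 19 stood higher at 6.22. Chromosome 19, the most gene-dense human chromosome, held 3.19 times its share (2.72 to 3.73). Without the segments it held 4.96 times its share, and chromosome 22 was then also called higher. Chromosomes 3, 17 and 1 held 2.31, 2.28 and 2.17 times their share, and chromosome 16 held 1.25 times its share (1.02 to 1.52, exact binomial test, adjusted p = 0.0291). These 6 chromosomes carried 67.8% of the regions on 23.9% of the sequence, and the shares of 16 of the 24 chromosomes were lower than their sequence. Chromosome Y, with 0 regions, is among the 16, and 15 were lower when it was left out. Whether these cells carry a chromosome Y was not examined, so its 0 regions are not read as depletion. Because shares add up to the whole, a low share on one chromosome follows in part from the high share of another. Among regions with a fifth-column value above 0, 3 chromosomes (16, 19 and 20) were higher and 8 lower, the calls of chromosomes 3, 17 and 1 ended at 1.35, 1.36 and 1.30 times, and chromosome 16 stood at 2.37 times. Of the 549 ZINBA regions with such a value, 381 stood in the shorter list, so this setting largely repeats that list. Fewer regions enter it, so calls can also end through lost power. Without the segments chromosome 17 fell to 1.44 times and chromosome 16 rose to 1.94 times, and at or above the median width chromosome 3 fell to 1.36 times.

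The shorter list was led by chromosomes 19, 17 and 16 instead. Chromosome 19 held 71 of its 785 counted regions, 5.50 times its share of the sequence (4.33 to 6.85, exact binomial test, adjusted p = 7.35e-29). Chromosome 17 held 3.26 times its share (2.57 to 4.07) and chromosome 16 held 2.32 times its share (1.74 to 3.03), with adjusted exact binomial p = 2.34e-16 and 4.57e-07. Chromosomes 20 and 1 followed at 1.89 times (1.29 to 2.66) and 1.73 times (1.44 to 2.05), with adjusted exact binomial p = 0.00295 and 3.01e-07. Chromosome 3 did not pass the test, at 1.27 times (0.993 to 1.60, exact binomial test, adjusted p = 0.0778). At or above the median width it was lower instead, at 0.622 times (exact binomial test, adjusted p = 0.0206), and it stood at 0.845 times among regions with a fifth-column value above 0 (adjusted exact binomial p = 0.639). Chromosome 18 had 3 regions, 0.146 times its share (0.0301 to 0.424, exact binomial test, adjusted p = 1.23e-05), and 9 chromosomes in all were lower, among them chromosome Y with 0 regions. Without the 4 segments the call of chromosome 20 ended, at 1.84 times (exact binomial test, adjusted p = 0.0515), chromosome 17 stood at 2.05 times, and 5 chromosomes were lower. Among regions with a fifth-column value above 0 the calls of chromosomes 17 (1.75 times, adjusted p = 0.0727) and 1 (1.36 times, adjusted p = 0.0919) ended in the exact binomial test.

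**Figure D1:**
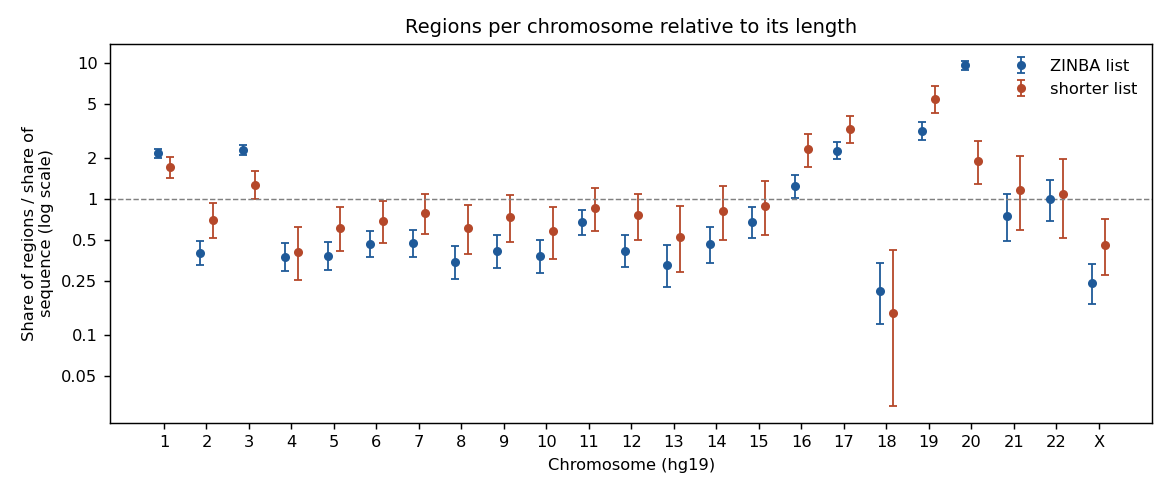
Share of regions divided by share of counted sequence for each chromosome with regions (log axis), in the ZINBA list (blue, 2910 regions) and the shorter list (red, 785 regions), with exact binomial 95% intervals as bars and the dashed line at equal shares. Chromosome 20 stands at 9.65 in the ZINBA list and 1.89 in the shorter list, while chromosome 19 stands at 3.19 and 5.50.

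By chromosome arm, 9 of 43 arms were higher in the ZINBA list, led by 20q at 14.1 times its share (12.97 to 15.29), 20p at 3.81 times and 3p at 3.77 times. Another 26 were lower, among them Yp and Yq with 0 regions each. In the shorter list 8 arms were higher and 10 lower, led by 19q at 5.68 times (4.12 to 7.61), 19p at 5.24 times and 17q at 3.98 times. The arm 3p passed there at 1.52 times (1.08 to 2.08, exact binomial test, adjusted p = 0.0328), although chromosome 3 as a whole did not.

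The share of ZINBA regions that also stood in the shorter list differed between chromosomes. On chromosome 20 it was 33 of 591 regions, or 5.58% (3.87 to 7.75), against 32.4% on the other chromosomes (Fisher's exact test, adjusted p = 3.24e-47). Chromosome 3 kept 15.0% (adjusted p = 8.28e-10) and chromosome 1 kept 21.4% (adjusted p = 0.00386), by the same exact test. Of the 23 chromosomes, 13 kept a higher share than the rest and 3 a lower one (Fisher's exact test, adjusted p under the threshold). The 13 ranged from 38.7% on chromosome 17 through 45.0% on chromosome 19 and 49.5% on chromosome 16 to 51.4% on chromosome X, and in each case the rest included chromosome 20.

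At the scale of cytogenetic bands, 47 of 792 bands held more ZINBA regions than their length would give and 31 held fewer. The densest was 20q13.2, a band that holds the transcription factor gene ZNF217 and the gene BCAS1, both known from amplified DNA in breast cancer. It had 284 regions, 53.3 times its share of the sequence (47.5 to 59.5). Band 3p14.1 had 208 regions (33.3 times, 29.0 to 37.9) and 1p13.3 had 147 (31.2 times, 26.4 to 36.5). Band 17q23.2, which holds BCAS3, TBX2 and the phosphatase gene PPM1D, had 81 regions (28.2 times, 22.5 to 35.0). These genes are named as landmarks of the bands, and no region was assigned to a gene.

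In the shorter list 13 bands were higher and 0 lower. With 785 counted regions over 792 bands, too few fell in each band for a lower share to be called. Of the 13, 11 were also higher in the ZINBA list, which holds every region of the shorter list. Band 17q23.1, which holds VMP1 and the microRNA gene MIR21, had 8 regions, 41.3 times its share (17.9 to 81.0), and 17q23.2 had 16 regions (20.7 times, 11.9 to 33.3). Band 11q13.1, the site of the long noncoding RNA genes NEAT1 and MALAT1, had 11 regions (15.9 times, 7.97 to 28.3). Chromosome 19 contributed 19q13.33 (10.6 times), 19q13.2 (9.23 times) and 19p13.3 (17 regions, 8.91 times, 5.21 to 14.2), and chromosome 16 contributed 16p13.3 (5.95 times) and 16p11.2 (5.56 times). Bands 1p34.1 and 7p22.1 were higher in the shorter list and not in the ZINBA list, which was not tested as a difference. The bands 20q13.2 and 3p14.1, densest in the ZINBA list, kept 4 of 284 (1.41%, 0.385 to 3.57) and 3 of 208 regions (1.44%, 0.298 to 4.16). Band 1p21.1 kept 0 of 70 (upper 95% bound 5.13%).

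By window of 1 Mb, the ZINBA list was densest at chromosome 1, 107000001 to 108000000 (180 regions), chromosome 3, 64000001 to 65000000 (173 regions), and chromosome 20, 53000001 to 54000000 (149 regions), 52000001 to 53000000 (127 regions) and 46000001 to 47000000 (57 regions), all in hg19. These 5 windows contributed 7, 3, 1, 1 and 0 regions to the shorter list. The median over the 1052 windows with any ZINBA region was 1. The densest windows of the shorter list were chromosome 17, 57000001 to 58000000 (11 of 22 ZINBA regions) and 59000001 to 60000000 (9 of 55), then chromosome 11, 65000001 to 66000000 (8 of 22), chromosome 1, 107000001 to 108000000 (7 of 180), and chromosome 16, 2000001 to 3000000 (6 of 9). The 8 regions on chromosome 11 lay between 65028501 and 65276750.

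**Figure D2:**
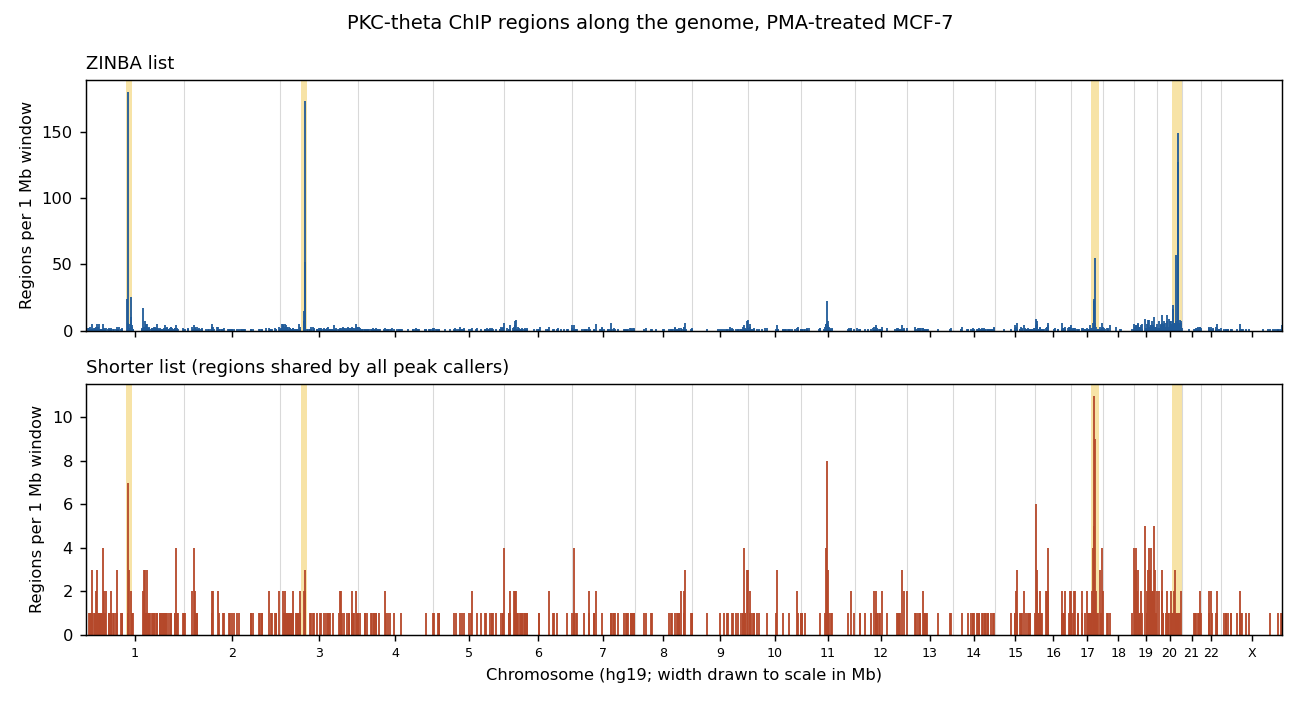
Number of regions in each window of 1 Mb along hg19 (horizontal axis, chromosomes drawn to scale) in the ZINBA list (upper panel) and the shorter list (lower panel, its own vertical scale), with yellow strips marking 4 segments known to be amplified in MCF-7 cells. The ZINBA list peaks at 180 regions on chromosome 1 and the shorter list at 11 regions on chromosome 17.

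MCF-7 cells carry extra copies of parts of 1p, 3p, 17q and 20q, and 4 such segments, chosen from background knowledge after the lists had been seen, were counted apart. Together they held 1088 ZINBA regions, 37.4% of the list on 2.72% of the sequence, 13.8 times their share (13.1 to 14.4). Among regions with a fifth-column value above 0 the fold was 5.76. They held 76 regions of the shorter list, 3.56 times their share (2.84 to 4.41). Of their ZINBA regions 6.99% (5.54 to 8.67) stood in the shorter list, against 38.9% (36.7 to 41.2) of the 1822 regions outside, an odds ratio of 0.118 for the shorter list against ZINBA-only (95% interval 0.0905 to 0.152, Fisher's exact test, adjusted p = 2.19e-89). The regions outside include the rest of chromosome 20. Relative to the sequence outside the segments, it stood at 6.10 times its share in the ZINBA list and 1.84 times in the shorter list. The odds ratio was 0.152 with chromosome 20 left out and 0.140 when compared within chromosomes. The segments were unlike each other. Segment 20q12-20q13 had 450 ZINBA regions (17.3 times) and kept 3.33%, segment 3p14 had 247 (15.6 times) and kept 2.83%, and segment 1p21.1-1p13 had 264 (16.5 times) and kept 5.30%. Segment 17q22-17q24 had 127 ZINBA regions (5.99 times) and kept 31.5% (23.5 to 40.3), which was not distinguishable from the regions outside (odds ratio 0.722, 0.478 to 1.08, Fisher's exact test, adjusted p = 0.109). In the shorter list this 17q segment held 6.99 times its share (5.03 to 9.43), 1p21.1-1p13 held 3.25 times (1.78 to 5.41), 20q12-20q13 held 2.13 times (1.20 to 3.50), and 3p14 did not pass the test at 1.64 times (0.662 to 3.37, exact binomial test, adjusted p = 0.213).

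Giemsa-pale bands are the gene-rich, early-replicating part of the chromosomes and made up 46.0% of the counted sequence. The shorter list had 60.0% of its regions there (471 of 785, 56.5 to 63.4), against 47.0% when the regions were placed at random on their own chromosomes (95% range 43.6 to 50.3, placement permutation test, two-sided p = 0.002, the smallest that 1000 placements can give). The ZINBA-only regions had 42.5% there (904 of 2125), below the 47.4% of random placement (permutation p = 0.002), a call that ended with the sign turned after merging within 1 kb (0.974 points above, permutation p = 0.448) and at fifth-column values above 0 (0.819 points above, permutation p = 0.883). The ZINBA list as a whole had 47.3%, against 47.2% (permutation p = 0.985), but it lay above random placement after merging within 1 kb (by 4.53 points), at or above the median width (4.41 points), without the 4 segments (13.4 points) and at fifth-column values above 0 (13.003 points), each with permutation p = 0.002. The odds ratio of lying in pale bands, shorter list against ZINBA-only, was 2.03 (1.71 to 2.40, Fisher's exact test, adjusted p = 8.52e-17). It was 1.55 without chromosome 20 and 1.35 when compared within chromosomes (Mantel-Haenszel), both past the threshold. Outside the 4 segments it was 1.08 (0.889 to 1.32, Fisher's exact test, adjusted p = 0.431), with 62.2% of the shorter list and 60.3% of ZINBA-only regions in pale bands, and there the ZINBA-only regions lay 12.4 percentage points above random placement whereas over the genome the difference was -4.86 points. The darkest bands held 5.99% of the shorter list and 6.01% of the ZINBA list on 17.6% of the sequence.

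**Figure D3:**
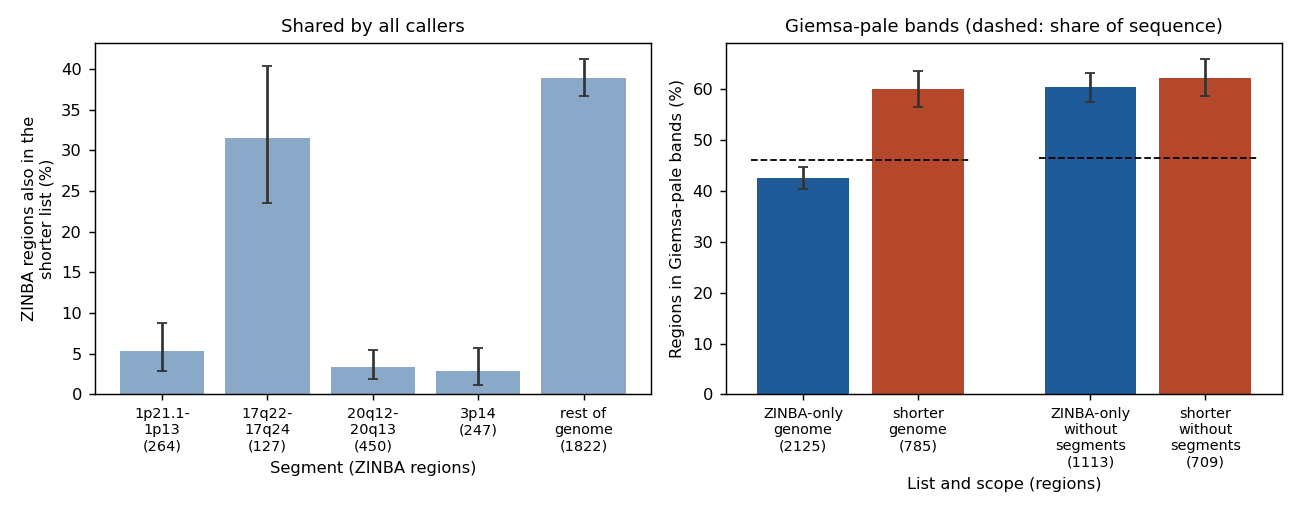
Left, percent of ZINBA regions that also stand in the shorter list, for each of 4 chromosome segments and the rest of the genome (number of ZINBA regions in brackets). Right, percent of ZINBA-only (blue) and shorter-list (red) regions in Giemsa-pale bands, over the genome and without the segments, with dashed lines at the share of sequence. Bars start at 0 and carry exact binomial 95% intervals. The 17q segment stands at 31.5%, near the 38.9% of the rest of the genome, while the others stand at 5.30% or below, and the pale-band difference of 60.0% against 42.5% shrinks to 62.2% against 60.3% without the segments.

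Regions also lay close to one another. In the ZINBA list 39.7% of regions had a neighbour within 10 kb, against 6.10% when placed at random, and in the shorter list 11.6% did, against 0.929% (placement permutation test, p = 0.002 for each). Part of this came from overlapping or adjoining pieces, since after merging within 1 kb the excess over random placement fell from 33.6 to 16.6 percentage points in the ZINBA list and from 10.7 to 1.43 points in the shorter list (permutation p = 0.002 and 0.01). Without the 4 segments the excess of the ZINBA list was 13.05 points, and at fifth-column values above 0 it was 7.71 points in the ZINBA list and 3.49 points in the shorter list. At or above the median width the excess was 25.4 points in the ZINBA list and 6.29 points in the shorter list. Among the 10 widest regions of the shorter list, the widest lay on chromosome 8 from 43092126 to 43097750 (5625 bp, band 8p11.21), 2.25 kb from the centromere band. The next lay within the centromere band of chromosome 6 from 58776126 to 58779875 (3750 bp, 6p11.1). A region on chromosome 1 from 121483626 to 121485875 (2250 bp, 1p11.2) lay 14.1 kb from the centromere band. Band 17q23.1 held 3 of the 10, from 57921376 to 57924000 (2625 bp), from 57919876 to 57922000 and from 57969251 to 57971375 (2125 bp each), of which the first pair overlap. The other 4 lay on chromosome 2 from 3521751 to 3524000 and chromosome 12 from 54672751 to 54675000 (2250 bp each), and on chromosome 10 from 134144501 to 134146625 and chromosome 16 from 3073001 to 3075125 (2125 bp each). The ZINBA list added 3 regions to its own 10 widest that were not in the shorter list, on chromosome 20 from 53009501 to 53012500 (3000 bp), chromosome 3 from 64899251 to 64901500 (2250 bp) and chromosome 1 from 107742376 to 107744500 (2125 bp).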

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

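All tests in this part were chosen after the values had been seen. The peak numbers of the ZINBA list run along the genome and rise with position on 23 of 23 chromosomes, but they are not complete. Up to the highest number, 9175, there are 6230 numbers with no listed region, and the comparisons of the report did not take them into account. Of these, 3977 lie within the run of chromosome 20, whose numbers take up 49.8% of all numbers and of which 12.9% are listed. Another 1161 lie within the run of chromosome 3, where 27.8% are listed, while on the other 21 chromosomes together 65.0% are listed. What the missing numbers stood for, and how they were left out, is not given in the sources used here and was not tested.

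The fifth column, used in the report only as an alternative, has a value of 1 to 9 in 549 ZINBA regions and 0 in the other 2396. A score of peak strength stays open, because the values point different ways. The values 1 to 9 did not rise with width (Spearman rho -0.0766 across regions, which are not independent, 95% interval -0.160 to 0.00712). Nor did they rise with standing in the shorter list (Spearman rho -0.0486, permutation p = 0.254). Regions above 0, however, were wider than those at 0 (mean 1457 ± 159 against 1341 ± 173 bp, SD over 549 and 2396 regions, permutation p = 1e-05, the smallest that 100000 resamples can give) and stood in the shorter list more often (69.4% against 17.3%). As plain small counts, a geometric decline fitted from 1 to 9 would put 78.9 regions above 9, and 0 were seen. The values 1 to 9 were distributed like first digits of numbers spread over many magnitudes (chi-square p = 0.641 against the leading-digit law, p = 1.94e-41 against equal shares). A candidate explanation is that numbers in scientific notation, such as p-values, were shortened to their first digit when the lists were written. The 2396 regions at 0 were outside this test, and the leading-digit law does not account for them. A geometric decline within 1 to 9 alone was not excluded either (chi-square p = 0.123). No biological explanation was tested.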

How the results depend on the processing

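Merging within 1 kb, keeping regions at or above the median width, leaving out chromosome Y and the stricter overlaps were planned for list sizes, overlap and chromosome shares; all other settings, among them merging and width for the other results, leaving out the 4 segments and keeping fifth-column values above 0, were chosen after the results were seen. Of 141 values computed for 32 results, 117 kept their direction and side of the threshold or stayed within their margin, 7 were weaker, 4 stronger, 6 reversed and 7 moved. This tally does not measure robustness. Some of the 117 were bound to stay, such as the overlaps, since the shorter list is a subset. They also include large falls, such as the ZINBA fold of chromosome 20 from 9.65 to 3.84 at fifth-column values above 0. The width setting kept 1490 ZINBA regions, because widths are tied, and gave chromosome 3 a fold of 0.622 in the shorter list, called lower (adjusted exact binomial p = 0.0206), in place of 1.27. With fifth-column values above 0 that fold was 0.845, 3 chromosomes were higher in each list, 8 were lower in the ZINBA list and 4 in the shorter list; fewer regions enter this setting. Without the segments 5 chromosomes were lower in the shorter list. The pale-band odds ratio fell to 1.08 without the segments, and the width difference became -21.8 bp after merging, which joins overlapping pieces into wider regions. The pale-band excess of the ZINBA list over random placement rose from 0.003 percentage points to 4.53 (merged), 4.41 (width), 13.4 (without segments) and 13.003 (values above 0), each with permutation p = 0.002. That of ZINBA-only regions went from -4.86 points to 0.974 (merged), 12.4 (without segments) and 0.819 (values above 0). Where no construction is named, the cause was not tested. The planned promoter, exon, gene list, motif, GC and repeat alternatives were not run. The width setting gave no random-placement value for the ZINBA-only list, whose median width is the narrowest. Unknown depth keeps regions missed at low coverage out of reach.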

Other observations

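All tests in this part were chosen after the results had been seen. Outside the 4 segments, pale bands held 62.2% of the shorter list and 60.3% of ZINBA-only regions on 46.3% of the sequence, and the darkest bands held 6.63% and 5.21% on 17.9%. Chromosome 20 stood there at 6.10 times its share in the ZINBA list and 1.84 times in the shorter list, a difference that was not tested. Of 48 bands tested against all other bands, segments included, 7 kept a lower share, all on 1p, 3p and 20q, and 3 a higher share of their ZINBA regions in the shorter list, namely 19p13.3, 19q13.2 and 16p11.2 with 17 of 22, 12 of 19 and 10 of 16 (Fisher's exact test, adjusted p = 1.13e-05, 0.00595 and 0.0144). The 38.9% kept outside the segments lies inside the intervals of 19q13.2 (38.4 to 83.7) and 16p11.2 (35.4 to 84.8) and below that of 19p13.3 (54.6 to 92.2). Band 11q13.1 kept 11 of 29, which did not pass the test (Fisher's exact test, adjusted p = 0.354). Centromere bands held 9 regions of the shorter list and 14 ZINBA-only regions, an odds ratio of 1.75 that was not distinguishable from 1 (0.664 to 4.35), and 3 of the 10 widest regions of the shorter list lay in or within 14.1 kb of a centromere band, where repeated sequence is common.

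The first pattern is the pile-up of ZINBA regions in 4 amplified segments. Listed pieces within 1 kb of each other would not account for it alone. After merging them the segments still held 10.5 times their share (9.81 to 11.2). Broad regions with pieces missing from the list stay open, because gaps wider than 1 kb are not merged. Of the peak numbers in the runs of chromosomes 20 and 3, 12.9% and 27.8% are listed. For 1p, 3p and 20q, extra DNA copies that raise the background and dense PKC-theta binding both stay open: the odds of also standing in the shorter list were 0.0611 of those outside (0.0420 to 0.0866), but these parts were set apart from 17q because that share was low, so the value adds no support, and the pooled fold of the shorter list was 2.31 (1.63 to 3.17) against 21.9 for ZINBA-only regions, with 3p14 alone at 1.64 (0.662 to 3.37), which did not pass the test. For 17q, copy number and dense binding cannot be told apart, because the odds ratio of 0.722 (0.478 to 1.08) leaves room for both and the fold of the shorter list, 6.99 (5.03 to 9.43), was close to the 5.62 of ZINBA-only regions. The input libraries, which would measure copy number directly, were not analysed here.

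The second pattern is the higher share of pale bands in the shorter list than among ZINBA-only regions. It may follow from the loss of regions in the 4 segments, because without them the odds ratio fell from 2.03 to 1.08 (0.889 to 1.32). Part of it was a difference between chromosomes, since within chromosomes the odds ratio was 1.35 and without chromosome 20 it was 1.55. Outside the segments the selection was not seen to favour pale bands, which held 62.2% of the shorter list and 60.3% of ZINBA-only regions. The interval of that odds ratio does not exclude a small preference. Both the shorter list and ZINBA-only regions lay above random placement there, by 15.0 and 12.4 percentage points. A preference of PKC-theta for gene-rich chromatin, and of sheared open chromatin for any ChIP, were not separated, because no untreated or input list was compared.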
